A study of Caenorhabditis elegans with 10 samples.

How the data were processed

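Poly-A-enriched RNA was sequenced from whole Caenorhabditis elegans at day 8 of adulthood, grown at the same temperature on the same bacterial food, per the labels' protocols. The 10 libraries form 2 groups of 5: wild type, and a mutant carrying the α3ΔN deletion of pas-3, taken from the titles and source names. The columns of the table name 5 wild type libraries by an abbreviation of their titles. The other 5 columns carry the letter A, which no label explains. They were taken as the mutant libraries because only that group was left, with the replicate number of the title. No label says whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

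The deposited table gives a value for each gene and library that the file headers name FPKM. FPKM usually means fragments per kilobase of gene, scaled to the fragments of the library. Here the scale did not follow the totals of the libraries, as given below. FastQC, HISAT2, featureCounts and DESeq2 are named, without versions, in the submitters' processing notes. FastQC inspects reads, HISAT2 aligns them, featureCounts counts them per gene and DESeq2 tests counts, in the submitters' use; their settings, the strand setting, and the genome build of the authors are not given in the sources used here. The FPKM totals of the libraries are unequal (mutant 726307 ± 11638, wild type 816432 ± 15849, mean ± SD, n = 5; exact permutation p = 0.00794, 2-sided, the smallest that 252 assignments allow). Each FPKM multiplied by the summed exon length of its gene gave whole multiples of 1 step per library for 58.9% to 61.9% of low values (up to 20 reads, tolerance 0.1 reads). The steps followed median-of-ratios size factors and not the totals. For 7699 genes the implied reads were whole in every library, which is too few for a count test, so FPKM was tested on a log scale.

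The table holds 25346 rows. Of these, 24885 matched 1 gene of the Ensembl WBcel235 annotation, from which names, coordinates (1-based) and exon lengths were taken; the authors' build may differ. A further 117 were features named as new by the authors and 344 did not match; both kinds together held 0.278% of the FPKM total on average and stayed in the tests. Implied totals of assigned fragments were 29381817, 26240310, 26886538, 24832631 and 26693056 in mutant libraries 1 to 5, and 28876966, 28267307, 29281799, 31499699 and 26300970 in wild type libraries 1 to 5. At the median exon length of 1302 bases, 1 FPKM stands for 32 fragments in the library with the smallest scale, with a 95% Poisson interval of 21.9 to 45.2 that covers counting error only. Members of families of near-identical copies (major sperm proteins, histones, vit-3 to vit-5, hsp-16 pairs, skr-7 and skr-8, cyp-31A copies, fipr and nspc genes) and overlapping or antisense genes have uncertain single values, because it is not given how such reads were assigned.

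Genes with at least 1 FPKM in at least 5 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, mutant against wild type, empirical Bayes with a mean-variance trend, 2-sided). Benjamini-Hochberg adjustment ran over all genes tested, and "rose" and "fell" refer to an adjusted p below 0.05. A fold change on this scale understates the change of genes with low FPKM. The planned filter was a value of at least 10, written for normalised counts; the table held FPKM, so the minimum was set to 1, and the literal minimum of 10 was run as an alternative. Levels are mean ± SD over 5 libraries.

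The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 35 gene lists were compared with the other genes by camera in limma with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. They were also tested with fry, which sets the members of a list against no change and not against the other genes. Member counts are given adjusted over all genes and adjusted over the list alone. Shares of the FPKM total were compared by an exact permutation test over 252 assignments, 2-sided. Named genes are pas-3, then the 10 genes per direction with the largest log2 fold change. These needed an adjusted p below 0.05, no overlap between groups and a mean of at least 50 FPKM in the higher group. Then follow up to 2 called members per list and direction with the smallest adjusted p, and 22 genes chosen for their known roles whatever their values. Gene name classes with at least 10 tested members were scanned with camera, and the share of called genes per chromosome was compared by Fisher's exact test.

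The procedure was tested on simulated data for the mutant against wild type comparison (13601 genes). It called 36.7% of genes changed by 1.25-fold, 62.5% at 1.5-fold, 87.5% at 2-fold and 100% at 4-fold, with 48 or 49 changed genes per fold. Of 13407 unchanged genes, 7 were called. The simulation drew genes independently and took their spread from the wild type libraries alone. In the data 44.4% of tested genes were called and mutant 3 stood apart, so these rates need not hold there. Alternatives were other pseudocounts (0.5 and 5), no filter, a mean of at least 50 FPKM, TMM scaling, quantile normalisation, robust empirical Bayes, array weights, the replicate number as a block, other gene set tests, and each library left out in turn. Alternatives added after the data were seen were a minimum of 10 FPKM, voom weights on implied reads, mutant 3 and wild type 1 left out together, and FPKM rescaled to equal totals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.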

Results

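Gene expression was measured in day 8 adults of Caenorhabditis elegans by sequencing poly-A RNA of 5 wild type libraries and 5 libraries of a mutant with a hyperactive proteasome. The mutant carries the α3ΔN deletion in pas-3, which encodes the α3 subunit of the 20S proteasome, the barrel-shaped core that degrades proteins. The deletion removes part of the amino-terminal tail of α3, a part of the gate through which substrates enter. The title of the series names translation, lipid metabolism and proteostasis, and the single comparison of mutant with wild type asks which transcripts of these and other groups differed at this age. Between 14168 and 14617 genes reached 1 FPKM per library, at an implied depth of 24832631 to 31499699 assigned fragments.

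The libraries separated by genotype. The first principal component of the log2 values held 62.9% of the variance and parted the groups, and the second held 7.32%. Correlations across genes were 0.982 to 0.989 within the mutant, 0.981 to 0.988 within wild type and 0.944 to 0.958 between the groups. Mutant 3 stood apart from the other mutant libraries on the second component and in several gene groups, as given beside them. Mitochondrially encoded transcripts took 0.548% of its FPKM total, against 0.889% to 0.984% in the other mutant libraries and 0.735% to 0.766% in wild type. Ribosomal RNA took 0.853%, against 0.124% to 0.291% and 0.155% to 0.195%.

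**Figure D1:**
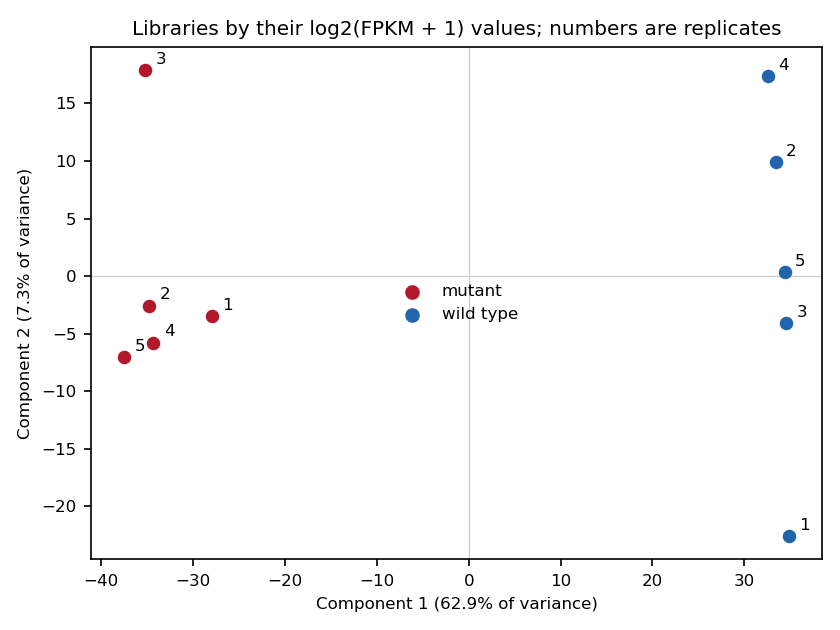
The plot sets the first principal component of log2(FPKM + 1) of the tested genes (horizontal, 62.9% of the variance) against the second (vertical, 7.32%), with 1 point per library and its replicate number. The 5 mutant libraries lie at negative and the 5 wild type libraries at positive values of the first component, and mutant 3 lies apart from the other mutant libraries on the second.

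pas-3 (Y110A7A.14, WBcel235 chromosome I, 5105110 to 5106048, minus strand), the edited gene, was measured at 167, 157, 127, 160 and 155.3 FPKM in mutant libraries 1 to 5. In wild type libraries 1 to 5 it stood at 183, 183, 189, 177 and 179 FPKM. The transcript fell by 0.25 on the log2 scale (SE 0.065, adjusted p = 0.00723), and all 5 mutant libraries lay below all wild type libraries. This call was lost with quantile normalisation (-0.09, adjusted p = 0.239) and with equal FPKM totals (-0.09, adjusted p = 0.256). A value over the whole gene hardly checks the labels, since a short deletion leaves most of the transcript in place.

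Of 14347 genes tested, 3069 rose and 3303 fell in the mutant. At least a 2-fold change was seen for 272 genes that rose and 435 that fell, and the median size of a called change was 0.41 on the log2 scale. Of all genes tested, 2284 had every mutant library above every wild type library and 2502 had every one below, where chance separates 0.794% of genes. The called genes among these were 2209 that rose and 2464 that fell. The balance of directions depended on the scaling. Of the calls, 48.16% were higher in the mutant with the values as deposited and 73.5% with FPKM rescaled to equal totals, a rescaling chosen after the data were seen, which moved the median of all genes from 0.01 to 0.16. Directions of genes and lists are therefore relative to the median gene.

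Most of the genes that rose most came from a near-zero wild type level. scl-24 (F08E10.7, chromosome V, 17486334 to 17487241), a gene of the SCP-like extracellular protein family, stood at 149 ± 16.3 FPKM in the mutant against 1.0703 ± 0.370 in wild type (log2 fold change 6.19, adjusted p = 3.18e-11). ins-31 (T10D4.4, chromosome II, 3127041 to 3127831), an insulin-like peptide gene, rose from 0.120 to 75.9 ± 25.02 FPKM (6.04). scl-25 (T19C9.5, chromosome V, 17225689 to 17227998) rose from 0.355 to 61.7 ± 6.03 FPKM (5.53). The same rule named Y74C10AR.2 (chromosome I, 2483203 to 2483652), K12H6.9 and its neighbour K12H6.4 on chromosome II, and F09C6.10 on chromosome V, all below 0.4 FPKM on average in wild type and between 51.4 and 90.3 FPKM in the mutant. From higher wild type levels, clec-190 (M199.4, chromosome IV, 15124931 to 15126121), a C-type lectin gene, rose 19.7-fold to 196 ± 21.6 FPKM. dhs-26 (chromosome X, 3360722 to 3362493), of the short-chain dehydrogenase family, rose 19.3-fold to 50.6 ± 5.05 FPKM, and C38D9.2 (chromosome V, 17567150 to 17571742) rose 9.15-fold to 105 ± 11.99 FPKM.

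Many of these genes belong to a larger set with the same distribution over libraries. In all, 54 genes were at 1 FPKM or less in every wild type library and at 5 FPKM or more in every mutant library, a criterion set after the values were seen, and 4 genes met its reverse. Among the 54 were 6 C-type lectin genes (clec-94, clec-96, clec-99, clec-137, clec-197 and clec-208), the astacin protease genes nas-17 and nas-24, the trypsin-like protease genes try-11 and try-13, scl-9, scl-15, scl-25 and ins-31. The FPKM of most differed between mutant libraries in the same way. The ratio of mutant 5 to mutant 1 was at least 1.5 for 53 of the 54, scl-25 being the exception at 0.994, and for 5.87% of all tested genes. Over those 53 genes, picked by that ratio, the median level relative to the gene's mutant mean was 0.536 in mutant 1 and 1.49 in mutant 5. Some markers of male sensory neurons were higher too. Of 9 such markers, cwp-1, cwp-2, pkd-2 and lov-1 lay above wild type in every mutant library, as did 2284 of all 14347 genes tested. cwp-3, cwp-4, cwp-5 and trf-1 overlapped (exact permutation p = 0.0635 to 0.556), as did asic-2, at 0.457 FPKM in the mutant and 0.563 in wild type. The ratio of lov-1 was 1.47, that of cwp-4 1.33 and that of asic-2 1.13. cwp-1, a gene of male-specific neurons, was at 5.15 ± 1.96 FPKM in the mutant and 0.193 ± 0.196 in wild type, with a mutant 5 to mutant 1 ratio of 3.11, and cwp-2 was at 5.32 ± 2.41 against 0.433 ± 0.303, with a ratio of 3.13. pkd-2, a polycystin gene of the same neurons, was at 0.582 ± 0.155 against 0.0521 ± 0.0124 FPKM, with a ratio of 1.95 (exact permutation p = 0.00794, adjusted 0.0437, n = 5 per group).

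**Figure D2:**
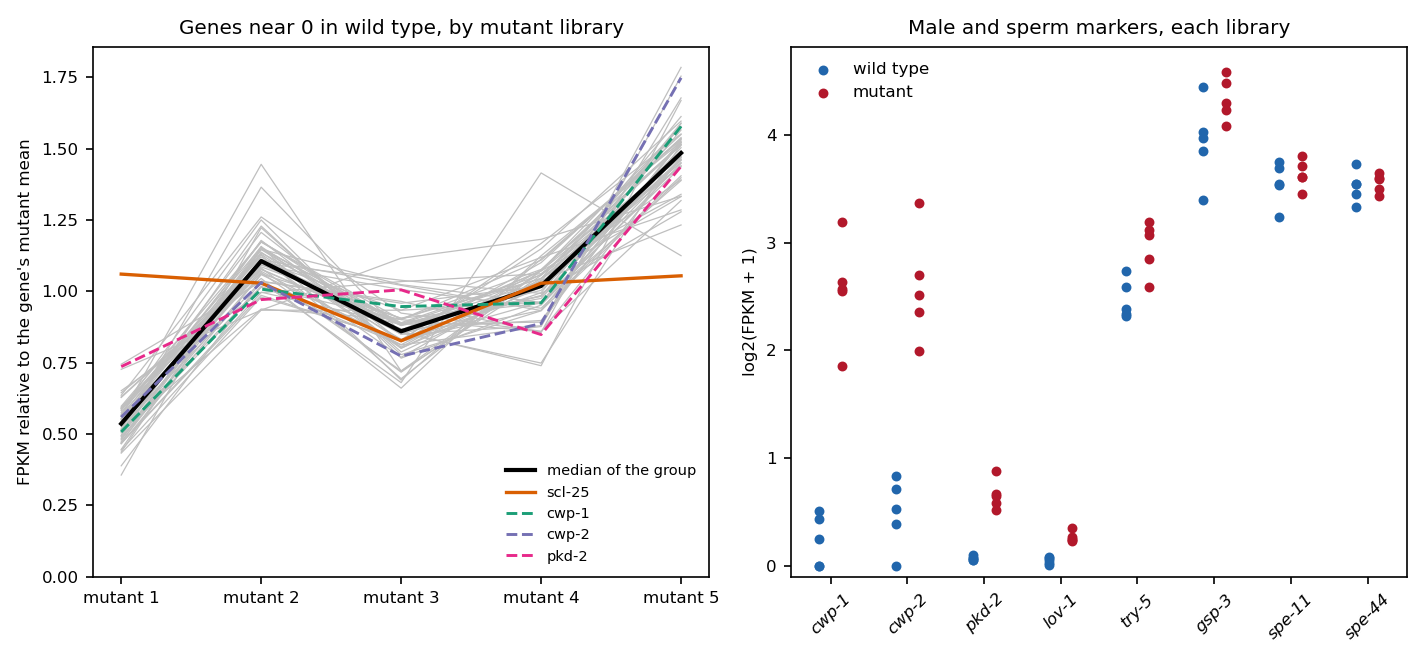
The left panel shows FPKM relative to the gene's mutant mean in each mutant library for 53 of the 54 genes near 0 in wild type (grey) and their median (black). These are the genes with a mutant 5 to mutant 1 ratio of at least 1.5, and their median ran from 0.536 in mutant 1 to 1.49 in mutant 5. The remaining gene, scl-25, and the male neuron markers cwp-1, cwp-2 and pkd-2 are drawn apart. The right panel shows log2(FPKM + 1) of male and sperm markers in each library, where the 5 mutant points of cwp-1, cwp-2, pkd-2 and lov-1 lie above the wild type points and those of spe-11 and spe-44 overlap them.

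The genes that fell most included cuticle collagens and a family of small peptides. nspc-9 (F42F12.1, chromosome X, 12342946 to 12343379), of the nematode-specific peptide family group c, fell from 120 ± 17.5 to 8.37 ± 2.30 FPKM (log2 fold change -3.72, 14.4-fold lower). nspc-1, nspc-10 and nspc-13, also on chromosome X, fell to 15.9, 38.8 and 20.54 FPKM from 134, 268 and 136 FPKM. These near-identical family members share sequence, so the value of a single copy is uncertain. col-19 (chromosome X, 421707 to 422691), a collagen of the adult cuticle, fell 6.96-fold from 687 ± 184 to 98.8 ± 13.3 FPKM. col-124 (chromosome IV, 10216451 to 10217617) fell from 308 to 27.2 FPKM and col-93 (chromosome III, 10984552 to 10985609) from 52.4 to 3.06 FPKM. C17H12.8 (chromosome IV, 6818703 to 6820575), C03G5.9 (chromosome X, 8535469 to 8535819) and drd-10 (chromosome V, 7007607 to 7008299) fell to 26.7, 35.5 and 9.10 FPKM from 228, 184 and 67.5 FPKM.

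Gene lists were compared with the remaining genes, and of the 35 lists 3 were higher and 13 lower in the mutant by camera with its preset correlation. No list passed with an estimated correlation (lowest adjusted p = 0.0734); fry, which asks if members move 1 way on balance, called 20 lists. The self-contained mixed test of fry called 34 lists. Equal FPKM totals raised the median of each list by 0.13 to 0.17. Member counts stand beside those of all 14347 genes tested, of which 3069 rose and 3303 fell. Counts near those proportions do not set a list apart.

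**Figure D3:**
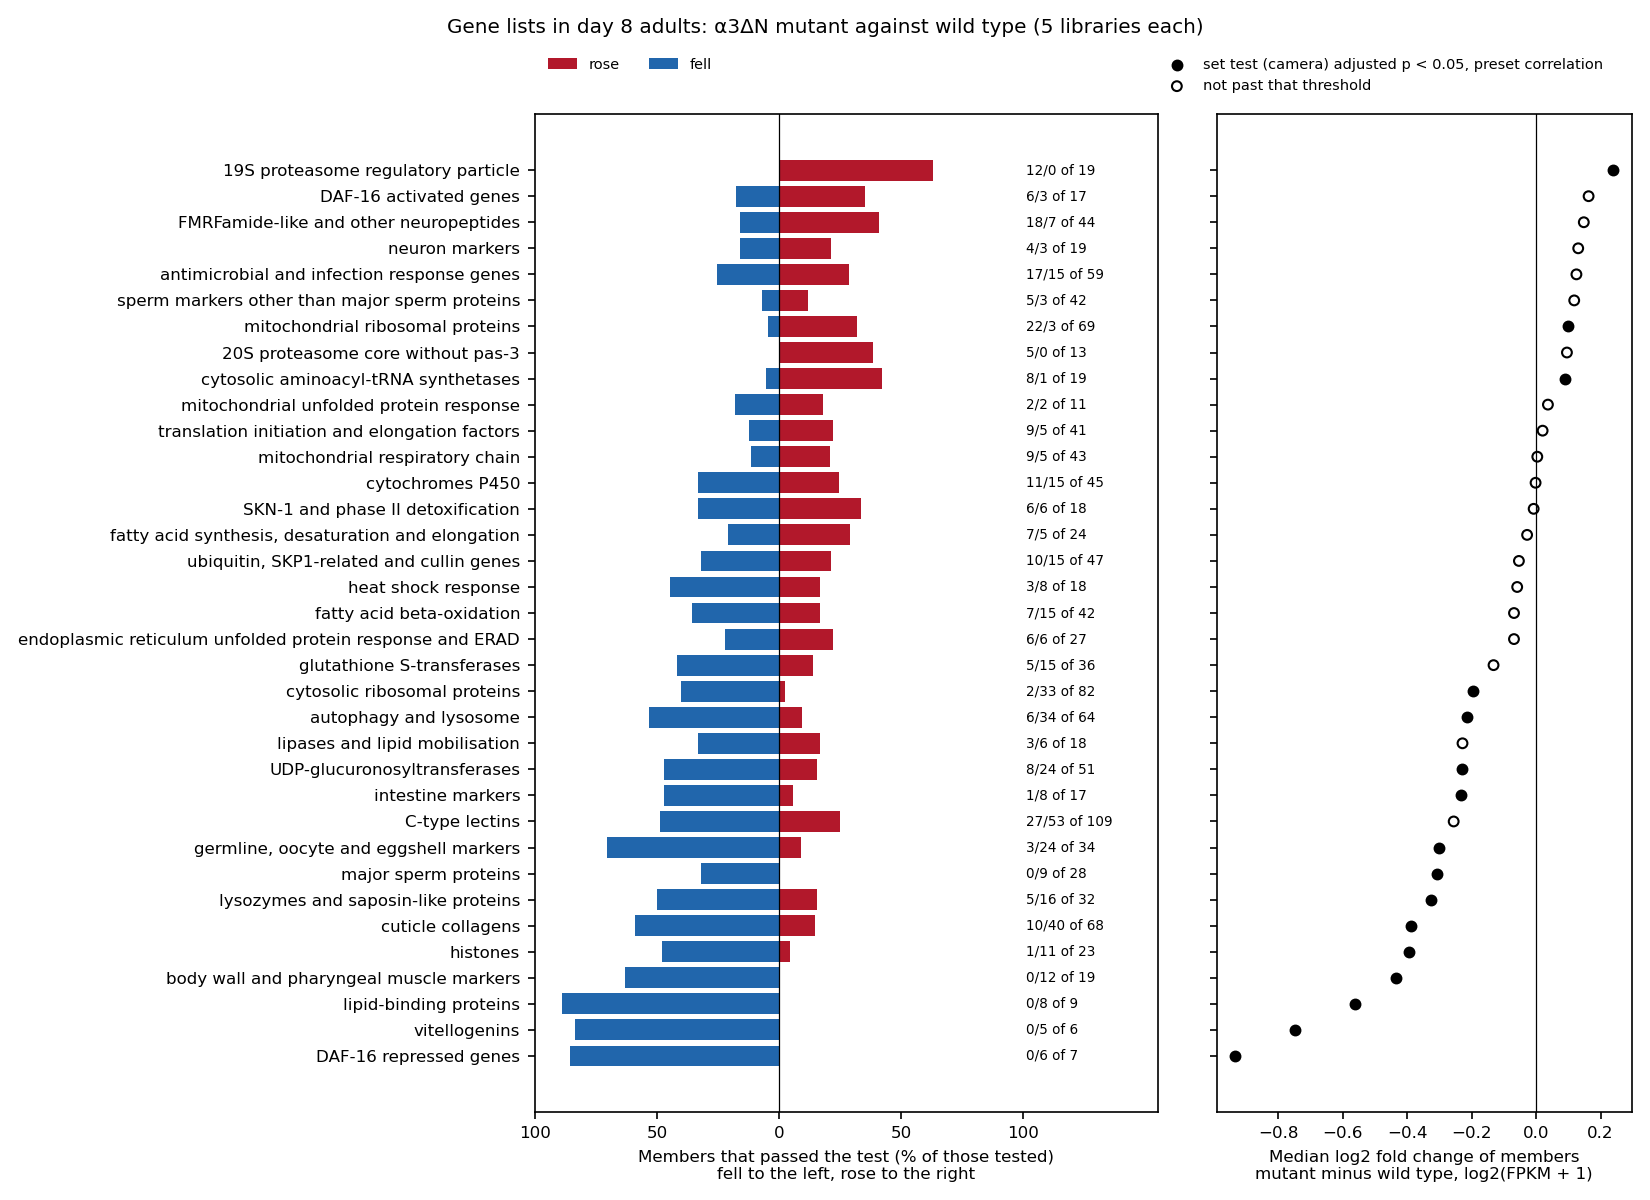
The left panel shows the percentage of tested members of each list that rose (right, red) or fell (left, blue), with the numbers beside the bars; the right panel shows the median log2 fold change of the members on log2(FPKM + 1), filled where camera passed with its preset correlation. The 19S proteasome list has the highest median (0.24) and the DAF-16 repressed list the lowest (-0.93), while the median of the cytosolic ribosomal list turned from -0.20 to 0.029 with quantile normalisation, and the lists with a median between -0.13 and 0.00 also changed sign under a scaling.

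More transcripts of the proteasome's regulatory particle rose than fell. Of 19 tested genes of the 19S particle, which recognises and unfolds ubiquitinated substrates, 12 rose, none fell and 7 did not pass (median 0.24, adjusted p = 6.33e-05 by camera, and adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, 13 rose. All 19 rose with quantile normalisation (median 0.36) and with equal FPKM totals (median 0.41). rpn-10, a ubiquitin receptor, rose from 93.4 ± 4.89 to 119.3 ± 3.40 FPKM (0.35, adjusted p = 4.56e-05). rpn-8 rose from 140 ± 4.10 to 178 ± 11.2 FPKM (0.35), and rpn-6.1, a subunit that stabilises the assembled proteasome, from 81.0 ± 2.59 to 98.3 ± 3.99 FPKM (0.28, adjusted p = 0.00019). Among the 13 other genes of the 20S core, 5 rose, none fell and 8 did not pass, and the count adjusted over the list alone was the same. pbs-6 rose from 161 ± 8.43 to 193 ± 8.87 FPKM (0.26) and pbs-4 from 103 ± 1.26 to 120 ± 9.82 FPKM (0.21). This list did not pass as a set (median 0.10, adjusted p = 0.071). It passed with quantile normalisation and with equal FPKM totals, where 11 rose (adjusted p = 0.000487 and 0.0033), and with array weights, without a filter, with a mean of at least 50 FPKM and on ranks (adjusted p = 0.0104 to 0.0454). It also passed without mutant 3 (9 rose, adjusted p = 0.00463), without mutant 3 and wild type 1 (adjusted p = 0.00234) and without wild type 5 (adjusted p = 0.0492). The 20S genes took 0.289% of the FPKM total in the mutant and 0.239% in wild type, and the 19S genes 0.343% and 0.267% (exact permutation p = 0.00794 for each, adjusted 0.0154).

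Ubiquitin pathway genes moved both ways, with more SKP1-related genes falling than rising. Of 47 ubiquitin, SKP1-related and cullin genes, 10 rose, 15 fell and 22 did not pass (12 and 16 adjusted over the list alone; adjusted p = 0.622), while 19 rose and 14 fell with quantile normalisation and 23 rose and 9 fell with equal FPKM totals. In the scan of gene name classes, 12 of 19 skr genes fell and 0 rose (median -0.37, adjusted p = 0.000498 by camera, and adjusted p = 0.774 with an estimated correlation). Of 19 ubc genes, 7 rose and 2 fell (median 0.09, adjusted p = 0.237 by camera). This division of the list was made after the values were seen. The conjugating enzyme genes ubc-25 and ubc-23 rose by 0.40 and 0.53. The SKP1-related genes skr-7 and skr-8, adaptors of ubiquitin ligases, fell to 37.0 ± 2.59 and 8.14 ± 1.26 FPKM from 75.5 ± 9.65 and 20.9 ± 3.34 FPKM.

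Chaperone genes moved both ways, in the endoplasmic reticulum and mitochondrial lists in about the proportions of all genes tested. In the heat shock list of 18 genes, 3 rose, 8 fell and 7 did not pass, the same adjusted over the list alone (adjusted p = 0.378). fry called this list lower (adjusted p = 0.0311), but with equal FPKM totals 6 rose and 4 fell, and with quantile normalisation 5 rose and 4 fell. Its share of the FPKM total was higher in the mutant, 0.494% against 0.462% (exact permutation p = 0.0159, adjusted 0.0278). That total was itself lower in the mutant (726307 against 816432), so the share does not show a rise of the list. hsp-16.2, a small heat shock protein that is induced by heat, fell from 2.18 ± 0.644 to 0.697 ± 0.228 FPKM (-0.89, adjusted p = 0.000813), hsp-70 fell by 0.43, and hsp-17 fell from 104.3 ± 9.45 to 52.0 ± 7.64 FPKM. hsp-12.6, a small heat shock gene under DAF-16 control, rose from 1.37 ± 0.601 to 7.10 ± 2.69 FPKM (1.75), and hsp-12.3 rose by 0.84. hsf-1, the heat shock transcription factor, rose by 0.13 (adjusted p = 0.0467), a call lost without a filter, with the replicate block, without mutant 3 and wild type 1 together, and in every fit that left out 1 library other than wild type 4 (adjusted p = 0.0521 to 0.111). Of 27 genes of the endoplasmic reticulum unfolded protein response and degradation, 6 rose, 6 fell and 15 did not pass, the same adjusted over the list alone (adjusted p = 0.671). The median of this list, -0.07, turned to 0.066 with quantile normalisation (10 rose, 3 fell) and to 0.0995 with equal FPKM totals (13 rose, 1 fell), while 5 rose and 10 fell without mutant 3. cnx-1 and enpl-1, both chaperones of the endoplasmic reticulum, rose by 0.23 and 0.27, dnj-27 fell by 0.48, and hsp-4, the BiP chaperone, fell by 0.14 (adjusted p = 0.0315). That call turned to 0.0092 with quantile normalisation and to 0.032 with equal FPKM totals, neither past the test, and was lost with the replicate block and without any 1 of mutants 1, 2, 4 and 5 or wild types 4 and 5 (adjusted p = 0.0603 to 0.0805). In the mitochondrial unfolded protein response list of 11 genes, 2 rose (dnj-10 and haf-1), 2 fell (dve-1 and hsp-60) and 7 did not pass, the same adjusted over the list alone (adjusted p = 0.622), while 7 rose and 1 fell with equal FPKM totals and 4 rose and 2 fell without mutant 3. hsp-60 lost its call without a filter, with quantile normalisation, with equal FPKM totals (adjusted p = 0.334), and without any 1 of mutants 1, 2, 4 and 5 or wild types 3, 4 and 5 (adjusted p = 0.0654 to 0.0814). hsp-6, a mitochondrial chaperone, was at 137 ± 18.99 FPKM in the mutant and 134 ± 11.5 in wild type (adjusted p = 0.776).

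More cytosolic ribosomal genes fell than rose with the values as deposited, a balance that depended on the scaling. Of 82 cytosolic ribosomal protein genes, 2 rose, 33 fell and 47 did not pass (2 and 32 adjusted over the list alone; median -0.20, adjusted p = 6.4e-05, and adjusted p = 0.727 with an estimated correlation), but with quantile normalisation 14 rose and 5 fell (median 0.029, adjusted p = 0.438), and with equal FPKM totals 9 rose and 9 fell. rps-13 fell from 1889 ± 167 to 1353 ± 84.3 FPKM (-0.48) and rpl-41.1 by 0.55, while rpl-24.2 rose by 0.41. These genes took 22.2% ± 0.820 of the FPKM total in the mutant and 22.6% ± 1.35 in wild type (exact permutation p = 0.627, n = 5 per group). Random lists of other genes, matched to them on exon length and level, had a median change of -0.23 (95% of matched lists from -0.33 to -0.17). The 236 distinct genes in these lists had a median change of -0.16. The aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher as a set: of 19 genes 8 rose, 1 fell and 10 did not pass, the same adjusted over the list alone (median 0.09, adjusted p = 0.0212, and adjusted p = 0.712 with an estimated correlation). This call was lost without wild type 2 (adjusted p = 0.0556), without mutant 3 and wild type 1 (adjusted p = 0.0579) and with array weights (adjusted p = 0.0559), while 11 rose and 0 fell with quantile normalisation and 17 rose and 0 fell with equal FPKM totals (median 0.26). lars-1 rose from 73.4 ± 2.51 to 105 ± 4.96 FPKM (0.52, adjusted p = 1.93e-06), fars-1 rose by 0.33, and the 1 gene that fell, yars-1, changed sign with equal FPKM totals (0.034) and lost its call with quantile normalisation, with the replicate block, and without any 1 of mutants 2 and 4 or wild types 3 and 4 (adjusted p = 0.0513 to 0.0914). Of 41 initiation and elongation factor genes, 9 rose, 5 fell and 27 did not pass, the same adjusted over the list alone (adjusted p = 0.629). This list was called higher with quantile normalisation (15 rose, 1 fell, adjusted p = 0.00203) and with equal FPKM totals (24 rose, 1 fell, adjusted p = 0.0215), while 11 rose and 10 fell without mutant 3. eif-2A rose by 0.30 and ife-5, a cap-binding protein gene, by 0.47, while ife-4 fell by 0.40. In mutant 3 this list took 2.48% of the FPKM total, against 2.06% to 2.11% in the other mutant libraries.

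Mitochondrial ribosomal genes rose more often than they fell. Of 69 genes, 22 rose, 3 fell and 44 did not pass, the same adjusted over the list alone (median 0.10, adjusted p = 0.00885, and adjusted p = 0.727 with an estimated correlation), and 31 rose without mutant 3. With equal FPKM totals 44 rose and 0 fell (median 0.26). The set call was lost by fry (adjusted p = 0.0826) and with a mean of at least 50 FPKM (adjusted p = 0.113). mrps-7 rose from 20.7 ± 0.604 to 31.3 ± 3.43 FPKM (0.57) and mrps-2 from 33.3 ± 2.66 to 50.4 ± 5.89 FPKM (0.58). In the respiratory chain list of 43 genes, 9 rose, 5 fell and 29 did not pass (7 and 4 adjusted over the list alone; adjusted p = 0.742). With quantile normalisation 21 rose and 2 fell and the set passed (adjusted p = 0.00312), and with equal FPKM totals 23 rose and 1 fell; without mutant 3, 12 rose and 8 fell. sdhb-1, a subunit of succinate dehydrogenase, rose from 140 ± 9.32 to 190 ± 11.5 FPKM (0.44), ucr-1 rose by 0.32, and ucr-2.3 fell from 80.1 ± 3.91 to 54.6 ± 1.94 FPKM (-0.54).

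**Figure D4:**
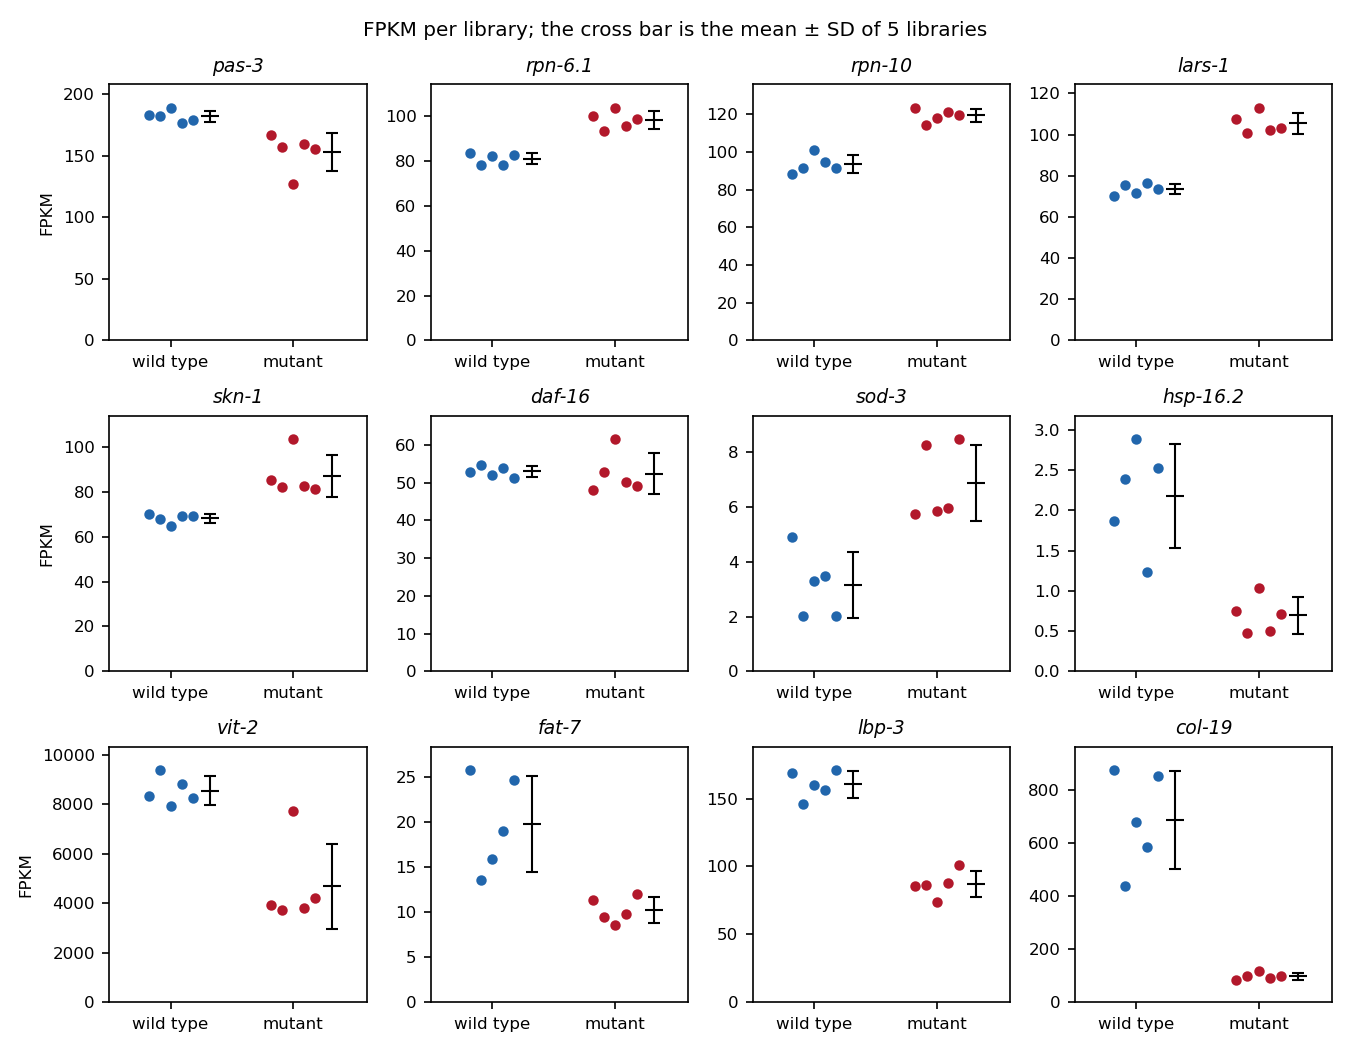
Each panel shows the FPKM of 1 gene (vertical axis, from 0) in the 5 wild type (blue) and 5 mutant (red) libraries, with the mean ± SD as a cross bar. The mutant points of rpn-6.1, rpn-10, lars-1, skn-1 and sod-3 lie above the wild type points, those of lbp-3, fat-7 and col-19 below, and mutant 3 is the high mutant point of vit-2 (7726 FPKM); the fall of pas-3 did not pass the test with quantile normalisation or equal FPKM totals.

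Most yolk and lipid transport genes fell. Of 6 vitellogenin genes, which encode yolk proteins made in the intestine, 5 fell and 1 did not pass, the same adjusted over the list alone (median -0.75, adjusted p = 0.0212, and adjusted p = 0.713 with an estimated correlation). The set call was lost with a minimum of 10 FPKM (adjusted p = 0.0555) and a mean of at least 50 FPKM (adjusted p = 0.138). vit-2 fell from 8544 ± 576 to 4681 ± 1714 FPKM (-0.93, adjusted p = 0.00131). Mutant 3 carried 7726 FPKM of vit-2, within reach of wild type, and the other mutant libraries 3715 to 4232 FPKM; without mutant 3 all 6 genes fell. vit-5 fell by 0.93 and vit-6 from 5225 ± 473 to 3265 ± 1458 FPKM (-0.76, adjusted p = 0.0108). The list took 1.77% ± 0.718 of the FPKM total in the mutant and 2.77% ± 0.227 in wild type (exact permutation p = 0.0397, adjusted 0.0631, n = 5 per group). All 9 lipid-binding protein genes but 1 fell, 8 in number also when adjusted over the list alone (median -0.56, adjusted p = 0.000368, and adjusted p = 0.371 with an estimated correlation). lbp-3 fell from 161 ± 10.1 to 86.96 ± 9.60 FPKM (-0.88) and lbp-6 from 109 ± 4.23 to 73.5 ± 7.05 FPKM (-0.56).

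Enzymes of lipid metabolism changed in both directions. Of 24 genes of fatty acid synthesis, desaturation and elongation, 7 rose, 5 fell and 12 did not pass, the same adjusted over the list alone (adjusted p = 0.934), while 11 rose and 5 fell with quantile normalisation and 12 rose and 4 fell with equal FPKM totals. The fatty acid desaturase genes fat-7 and fat-5 fell from 19.8 ± 5.34 to 10.2 ± 1.43 FPKM (-0.86, adjusted p = 0.00105) and by 0.58, and fat-6 fell by 0.21, a call lost with equal FPKM totals (adjusted p = 0.466). sbp-1, the SREBP transcription factor of lipid synthesis, fell by 0.37 (adjusted p = 0.00146), and the elongases elo-2 and elo-4 rose by 0.40 and 0.57. nhr-49, a nuclear receptor that controls fat use, was at 56.4 ± 1.46 against 53.1 ± 0.602 FPKM (adjusted p = 0.0676) and passed without a filter (adjusted p = 0.0457), with quantile normalisation (adjusted p = 0.0125) and with equal FPKM totals (adjusted p = 0.000235). In the beta-oxidation list of 42 genes, 7 rose, 15 fell and 20 did not pass, the same adjusted over the list alone (adjusted p = 0.137). fry called it lower (adjusted p = 0.00578), as did camera without a filter (adjusted p = 0.0492), but with equal FPKM totals 13 rose and 9 fell. acs-2, an acyl-CoA synthetase gene, rose 3.77-fold to 6.34 ± 1.503 FPKM (1.46) and hacd-1 rose 2.07-fold, whereas the carnitine palmitoyltransferase genes cpt-4 and cpt-6 fell by 1.104 and 1.08. Of 18 lipase genes, 3 rose, 6 fell and 9 did not pass, the same adjusted over the list alone (adjusted p = 0.142), and fry called the list lower (adjusted p = 0.00199). Its share of the FPKM total was higher in the mutant, 0.0492% against 0.0404% (exact permutation p = 0.00794, adjusted 0.0154). lips-11 fell from 16.98 ± 3.58 to 2.22 ± 0.864 FPKM (-2.50) and the lysosomal lipase gene lipl-7 by 0.86, and lips-15 rose from 83.4 ± 7.21 to 156 ± 9.57 FPKM (0.90).

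Among stress and longevity regulators, skn-1, which drives antioxidant and detoxification genes, rose from 68.1 ± 1.97 to 86.95 ± 9.42 FPKM (0.34, adjusted p = 0.000984). pqm-1, a transcription factor that acts opposite to DAF-16, fell from 46.6 ± 1.28 to 34.8 ± 2.34 FPKM (-0.41, adjusted p = 4.56e-05). daf-16, the FOXO factor of insulin signalling, was at 52.4 ± 5.45 against 53.0 ± 1.42 FPKM (adjusted p = 0.808). In the list of SKN-1 and phase II detoxification genes, 6 of 18 rose, 6 fell and 6 did not pass, the same adjusted over the list alone (adjusted p = 0.934). nit-1, a nitrilase gene, rose 3.90-fold (1.71), gcs-1, the enzyme that limits glutathione synthesis, rose by 0.20 (adjusted p = 0.00356), and gst-10 fell by 1.34. gst-4, a common SKN-1 reporter, was at 24.4 ± 2.75 against 34.03 ± 10.7 FPKM (adjusted p = 0.0834), and passed without wild type 2 (adjusted p = 0.0108) and with array weights (adjusted p = 0.0472). Of 17 DAF-16 activated genes, 6 rose, 3 fell and 8 did not pass, the same adjusted over the list alone (adjusted p = 0.234), and fry called the list higher (adjusted p = 0.00371). sod-3, a mitochondrial superoxide dismutase gene, rose 2.19-fold from 3.14 ± 1.20 to 6.87 ± 1.38 FPKM (0.96, adjusted p = 0.00142). Of 7 DAF-16 repressed genes, 6 fell and 1 did not pass, the same adjusted over the list alone (median -0.93, adjusted p = 0.000418, and adjusted p = 0.0734 with an estimated correlation). They include vit-2 and vit-5, which the vitellogenin list also holds, the insulin-like gene ins-7, which fell from 132 ± 12.5 to 48.0 ± 9.19 FPKM (-1.46), and dod-23, which fell by 1.247.

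Genes of conjugating detoxification enzymes fell more often than they rose. Of 51 UDP-glucuronosyltransferase genes, whose products conjugate lipophilic compounds, 8 rose, 24 fell and 19 did not pass (10 and 28 adjusted over the list alone; median -0.23, adjusted p = 0.00845, and adjusted p = 0.611 with an estimated correlation). The set call was lost with a minimum of 10 FPKM (adjusted p = 0.249) and a mean of at least 50 FPKM (adjusted p = 0.277), and with equal FPKM totals 13 rose and 18 fell (median -0.07). ugt-63 fell from 11.5 ± 1.15 to 3.69 ± 0.221 FPKM (-1.41), ugt-29 fell by 0.78 and ugt-64 rose by 0.53. Of 36 glutathione S-transferase genes, 5 rose, 15 fell and 16 did not pass, the same adjusted over the list alone (adjusted p = 0.081); the list passed as lower by fry (adjusted p = 0.0114), with a minimum of 10 FPKM (adjusted p = 0.00273), with quantile normalisation (adjusted p = 0.0332) and with equal FPKM totals (adjusted p = 0.0184), where its median turned from -0.13 to 0.00401. gst-24 fell from 646 ± 78.5 to 209 ± 22.2 FPKM (-1.62) and gst-36 by 1.06. Of 45 cytochrome P450 genes, 11 rose, 15 fell and 19 did not pass (12 and 16 adjusted over the list alone; adjusted p = 0.757), and with equal FPKM totals 16 rose and 9 fell. cyp-13A5 fell from 13.7 ± 7.39 to 1.59 ± 0.322 FPKM (-2.39).

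More genes of a list of autophagy and lysosome genes fell than rose, largely vha and asp genes. In the autophagy and lysosome list of 64 genes, 6 rose, 34 fell and 24 did not pass (6 and 35 adjusted over the list alone; median -0.21, adjusted p = 6.33e-05, and adjusted p = 0.0734 with an estimated correlation). With quantile normalisation 9 rose and 23 fell (median -0.064), and with equal FPKM totals 15 rose and 22 fell (median -0.046). Of its 20 vha genes (proton pump) 17 fell and 1 rose, of 10 asp genes (aspartyl proteases) 8 fell and 1 rose, and of 12 atg genes (autophagy) 2 fell and 1 rose (median 0.00437), a division made after the values were seen. asp-2, an aspartyl protease gene, fell from 170 ± 9.03 to 79.5 ± 6.58 FPKM (-1.09) and epg-2, an adaptor for degradation of protein aggregates, from 31.1 ± 3.98 to 8.496 ± 0.372 FPKM (-1.75). bec-1, the Beclin of autophagosome formation, rose from 26.4 ± 1.63 to 40.3 ± 1.51 FPKM (0.59) and epg-8 rose by 0.25. hlh-30, the TFEB factor of lysosomal genes, and sqst-1, a receptor of selective autophagy, were at 58.9 ± 7.92 and 92.9 ± 10.6 FPKM against 57.1 ± 2.83 and 89.1 ± 2.51 FPKM (adjusted p = 0.714 and 0.535), both highest in mutant 3; sqst-1 passed with equal FPKM totals (adjusted p = 0.0243). lgg-1, a ubiquitin-like protein of the autophagosome, was at 588 ± 62.9 against 665 ± 18.5 FPKM (adjusted p = 0.0556). It passed with a mean of at least 50 FPKM, a minimum of 10 FPKM, array weights or voom, changed sign with quantile normalisation, and passed without mutant 3, alone or together with wild type 1 (adjusted p = 0.0152 and adjusted p = 0.0276), where that library held 476 FPKM.

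Defence genes changed in large numbers and in both directions. Of 109 C-type lectin genes, which encode secreted or membrane sugar-binding domains, 27 rose, 53 fell and 29 did not pass (29 and 53 adjusted over the list alone). Their median was -0.26 but their mean 0.06, and the set test leaned lower without passing (adjusted p = 0.0604). It passed without wild type 1, alone or together with mutant 3, and without wild type 5 (adjusted p = 0.0425, 0.041 and 0.0492). The set also passed with quantile normalisation, equal FPKM totals, a pseudocount of 5, either stricter filter, voom and fry (adjusted p = 0.000109 to 0.0405). clec-41 fell from 334 ± 22.9 to 126 ± 7.71 FPKM (-1.40) and clec-169 by 2.56, and clec-197 rose from 0.173 to 47.04 ± 14.4 FPKM; clec-197 belongs to the 54 genes near 0 in wild type. Of 32 lysozyme and saposin-like genes, 5 rose, 16 fell and 11 did not pass, the same adjusted over the list alone (median -0.33, adjusted p = 0.00659, and adjusted p = 0.713 with an estimated correlation). lys-8 fell by 0.71, spp-18 from 114 ± 3.77 to 25.9 ± 5.52 FPKM (-2.12), and spp-9 rose from 12.099 ± 6.26 to 80.5 ± 18.8 FPKM (2.74). lys-7 fell by 0.41, a call that changed sign with quantile normalisation (0.0081) and was lost with equal FPKM totals. Of 59 antimicrobial and infection response genes, 17 rose, 15 fell and 27 did not pass, the same adjusted over the list alone (adjusted p = 0.622). irg-4 (-1.69) and pals-24 (-1.254) fell; fipr-28, another of the 54 genes, rose from 0.0736 to 26.4 ± 11.99 FPKM, and fipr-17 rose to 7.33 ± 2.53 FPKM from being listed at 0 in each wild type library.

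More structural genes of the cuticle and of muscle fell than rose. Of 68 cuticle collagen genes, 10 rose, 40 fell and 18 did not pass (11 and 41 adjusted over the list alone; median -0.39, adjusted p = 6.4e-05, and adjusted p = 0.371 with an estimated correlation). The set call was lost when genes of low FPKM were kept (adjusted p = 0.24). The collagens took 1.61% ± 0.0535 of the FPKM total in the mutant and 2.40% ± 0.156 in wild type (exact permutation p = 0.00794, adjusted 0.0154, n = 5 per group). col-179 fell from 31.4 ± 4.203 to 9.59 ± 1.11 FPKM (-1.61), and col-41 and col-144 rose by 1.30 and 0.88. Of 19 muscle genes, 12 fell, none rose and 7 did not pass, the same adjusted over the list alone (median -0.43, adjusted p = 0.00459, and adjusted p = 0.727 with an estimated correlation). The troponin genes unc-27 and pat-10 fell from 229 ± 40.5 to 128 ± 13.6 FPKM (-0.83) and from 601 ± 86.98 to 342 ± 47.9 FPKM (-0.81). In mutant 3, pat-10 was at 259 FPKM, and 15 muscle genes fell without that library.

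More markers of the intestine and the female germline fell than rose. Of 17 intestine genes, 1 rose, 8 fell and 8 did not pass (2 and 9 adjusted over the list alone; median -0.23, adjusted p = 0.00459, and adjusted p = 0.117 with an estimated correlation). The set call was lost with a mean of at least 50 FPKM (adjusted p = 0.459), and with equal FPKM totals 3 rose and 7 fell (median -0.065). cpr-6, a cathepsin B gene, fell from 698 ± 68.2 to 392 ± 10.5 FPKM (-0.82) and the proton exchanger gene nhx-2 by 0.79, while the peptide transporter gene pept-1 rose by 0.28. Of 34 germline, oocyte and eggshell genes, 3 rose, 24 fell and 7 did not pass, the same adjusted over the list alone (median -0.30, adjusted p = 6.42e-06, and adjusted p = 0.371 with an estimated correlation). With quantile normalisation 5 rose and 15 fell (median -0.11), and with equal FPKM totals 4 rose and 13 fell (median -0.13). cav-1, the caveolin gene, fell from 179 ± 23.5 to 33.9 ± 2.05 FPKM (-2.36) and oma-2, needed for oocyte maturation, from 296 ± 24.2 to 112 ± 7.32 FPKM (-1.39), while meg-1 and glh-2, both of germ granules, rose by 0.43 and 0.21. The share of this list, 1.88% ± 0.151 against 1.99% ± 0.0516, did not differ past the test (exact permutation p = 0.206, n = 5 per group), with 2.15% in mutant 3. Of 28 major sperm protein genes, which have near-identical copies, 9 fell, none rose and 19 did not pass, the same adjusted over the list alone (median -0.31, adjusted p = 0.0118, and adjusted p = 0.757 with an estimated correlation); the call was lost without wild type 4 (adjusted p = 0.0854), by fry (adjusted p = 0.16) and with a minimum of 10 FPKM (adjusted p = 0.189). msp-152 fell by 1.27. Of 42 other sperm genes, 5 rose, 3 fell and 34 did not pass (3 and 3 adjusted over the list alone; adjusted p = 0.462), with spe-6 up by 0.35 and ssq-2 down (-0.78).

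More histone genes fell than rose, and the balance of neuron markers depended on the scaling. Of 19 neuron markers, 4 rose, 3 fell and 12 did not pass, the same adjusted over the list alone (adjusted p = 0.512), while 12 rose and 1 fell with equal FPKM totals (median 0.27). eat-4, a glutamate transporter gene, rose by 0.47 and unc-25, which makes GABA, fell by 0.54. Of 44 neuropeptide genes, 18 rose, 7 fell and 19 did not pass, the same adjusted over the list alone (median 0.15, adjusted p = 0.0921), and the set passed without mutant 3, alone or together with wild type 1 (adjusted p = 0.0176 and 0.0157), and with array weights (adjusted p = 0.0216). nlp-18 rose from 21.7 ± 2.92 to 37.2 ± 2.74 FPKM (0.76), flp-6 fell by 0.52, and flp-23 rose to 2.86 ± 1.54 FPKM from being listed at 0 in each wild type library. Of 23 histone genes, 1 rose, 11 fell and 11 did not pass, the same adjusted over the list alone (median -0.39, adjusted p = 0.00336, and adjusted p = 0.487 with an estimated correlation). The linker histone gene his-24 fell from 70.1 ± 4.46 to 27.5 ± 3.40 FPKM (-1.33) and his-71, a replacement variant, rose by 0.35; most histone messages lack a poly-A tail, so this preparation samples them incompletely.

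Shares of the FPKM total differed for 20 of the 35 lists, of which 12 were higher in the mutant (exact permutation test, smallest p the design allows 0.00794). Because the FPKM total was lower in the mutant, a share can be higher where the list median did not change. The respiratory chain took 1.04% ± 0.00844 against 0.926% ± 0.0209 and fatty acid synthesis 0.427% ± 0.0209 against 0.335% ± 0.0318 (adjusted p = 0.0154 for each by the exact permutation test, n = 5 per group).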

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

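Each value here lay apart from the other 4 libraries of its group by a gap test chosen in advance, and no test in this part was chosen after its result was seen. For independent, unselected values chance does so in about 1 of 20 groups. Of the 390 groups of 5 values 50 did, 40 of them in mutant 3, the rest in mutants 1 and 5 and wild types 2, 3 and 5. Many groups share genes or were picked by their test results, so this rate is a rough guide. The 40 values of mutant 3 are not separate findings.

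In mutant 3 the yolk genes were at levels closer to wild type: vit-2 at 7726 FPKM (3715 to 4232 in the other mutant libraries), vit-5 at 7706 FPKM (3646 to 4094) and vit-6 at 5851 FPKM (2461 to 2937). Vitellogenins took 3.05% of its FPKM total against 1.38% to 1.56%, and the DAF-16 repressed list, which holds vit-2 and vit-5, 2.22% against 1.068% to 1.18%. Regulators and stress genes also stood high there: skn-1 103.6 FPKM, hsf-1 36.2, hlh-30 72.9, sbp-1 19.8, hsp-6 169.9, hsp-60 61.5, enpl-1 366 and sqst-1 111.3 FPKM. So did ife-5 (12.7 FPKM), sdhb-1 (210.1), ucr-1 (185), col-41 (5.07), meg-1 (107) and glh-2 (54.001). Low in mutant 3 were scl-24 (120.4 FPKM), scl-25 (51.02), lgg-1 (476), pbs-4 (102.6), rpl-24.2 (149.6), gst-24 (169.4), hil-1 (26.7), clec-169 (0.552) and pat-10 (259).

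Shares of the FPKM total that were high in mutant 3 were those of translation factors (2.48%), aminoacyl-tRNA synthetases (0.2505%), the heat shock list (0.565%), the endoplasmic reticulum list (0.6365%), germline and eggshell markers (2.15%) and intestine markers (0.288%). Low there were the shares of the 20S core (0.267%), ubiquitin genes (0.830%), cytosolic ribosomal proteins (20.8%), mitochondrial ribosomal proteins (0.254%), glutathione S-transferases (0.0918%) and lysozymes (1.57%).

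In other libraries, pqm-1 was low in mutant 5 (30.8 FPKM) and cav-1 high in mutant 1 (37.5 FPKM). Wild type 2 was high for C38D9.2 (14.009 FPKM), cyp-29A2 (22.3 FPKM), the autophagy and lysosome share (1.49%) and the C-type lectin share (0.613%). Wild type 3 was low for scl-25 (0.112 FPKM) and high for nspc-1 (147.1 FPKM) and elo-2 (26.0 FPKM), and wild type 5 was high for rpl-41.1 (178.6 FPKM).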

How the results depend on the processing

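Alternatives chosen after the data were seen were the minimum of 10 FPKM, voom, the joint removal of mutant 3 and wild type 1, equal FPKM totals, and all alternatives for the principal components, the gene class scan, the chromosome test and the genes near 0; the rest were planned. Of the 153 named genes called, 137 kept direction and call under every alternative that tested them, and all 7 not called passed or moved under at least 1. The stricter filters left some named genes untested, and those count as kept there. Of the 16 lists called, 8 kept their call under every alternative other than the estimated correlation, with which camera passed 0 higher and 0 lower lists (4 lists at an unadjusted p under 0.05, and 20 by fry). Calls in the opposite direction numbered 7 of 14347 genes with quantile normalisation and 0 otherwise. Leaving out 1 library gave 2742 to 3280 genes that rose and 3005 to 3448 that fell, 2 (without wild type 2) to 5 (without mutant 3) lists higher and 2 (without mutant 2 or wild type 5) to 5 chromosomes with an uneven share of calls (4 with all libraries). A pseudocount of 5 gave 125 and 194 genes at least 2-fold higher and lower, because a larger pseudocount shrinks small values. With fewer genes tested, a mean of at least 50 FPKM gave 557 genes that rose and 914 that fell, 8 and 95 at 2-fold, and 7 gene classes. The minimum of 10 FPKM gave 1982 that rose, 91 and 236 at 2-fold, and 15 classes. Without a filter 7 chromosomes had an uneven share. Voom gave 457 genes at least 2-fold higher. Quantile normalisation gave 6 lists higher and reversed the ribosomal list (median 0.029), hsp-4 (0.0092) and lys-7 (0.0081), none past the test. Equal FPKM totals gave 5484 genes that rose, 1975 that fell and 5 lists higher, and reversed hsp-4 (0.032) and yars-1 (0.034); this scaling raises all mutant values and moves the median of all genes from 0.011 to 0.16. The cause of the voom, no filter and quantile changes was not tested. The values showed no pairing by replicate number, which does not tell whether libraries were prepared in pairs. Deviations of same-numbered libraries correlated between -0.04 and 0.02, and 0 of 10 libraries correlated best with its own number. With the number as a replicate block, 2856 genes rose and 3124 fell, 5809 of 6372 calls keeping their direction, and 0 list shares passed the sign-flip test, whose lowest p of 0.0625 with 5 pairs cannot pass. Planned count tests with edgeR and DESeq2 were not run, because whole reads came back for too few values. Depth limits genes near 1 FPKM, where 32 fragments carry a 95% interval of 21.9 to 45.2.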

Other observations

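The tests of major sperm proteins, of linkage and of muscle, intestine and neuron markers were chosen only after the result was seen, as were the set of 54 genes and the ratio of group means of male markers; the gene examples of the class scan were chosen after their values were seen. Several families in a scan of gene name classes were lower. Of 124 classes, 7 were higher and 16 lower by camera with its preset correlation, and 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05. The medians of the families named here kept their sign with TMM scaling, quantile normalisation and equal FPKM totals, the vha median lying between -0.31 and -0.14. Of 16 nspc genes, 15 fell and none rose (median -2.56, adjusted p = 3.98e-14, and adjusted p = 0.104 with an estimated correlation). Of 29 fbxb genes, which encode F-box proteins that can recruit substrates to ubiquitin ligases, 25 fell and none rose (median -0.90, adjusted p = 6.82e-08, and adjusted p = 0.267 with an estimated correlation). fbxb-91 fell from 3.95 ± 1.01 to 0.335 ± 0.161 FPKM. Of 20 vha genes, which encode subunits of the proton pump that acidifies lysosomes, 17 fell and 1 rose (median -0.31, adjusted p = 1.11e-05, and adjusted p = 0.267 with an estimated correlation), vha-5 from 63.6 ± 2.29 to 35.7 ± 1.96 FPKM. The autophagy and lysosome list holds these genes too. Of 49 transthyretin-like genes, 27 fell and 9 rose (median -0.38, adjusted p = 0.0045, and adjusted p = 0.879 with an estimated correlation), with ttr-16 at 971 ± 107 FPKM against 2327 ± 203.

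Other families were higher. Of 26 npp genes, which encode nuclear pore proteins, 14 rose and 2 fell (median 0.14, adjusted p = 0.0257, and adjusted p = 0.784 with an estimated correlation). npp-24 rose from 21.3 ± 1.18 to 29.9 ± 1.81 FPKM. Of 31 vps genes, which encode vesicle sorting proteins, 12 rose and none fell (median 0.12, adjusted p = 0.0436, and adjusted p = 0.611 with an estimated correlation), vps-8 from 16.99 ± 0.478 to 25.02 ± 1.20 FPKM. Among 12 scl genes, 7 rose and 3 fell (median 1.96, adjusted p = 0.00105, and adjusted p = 0.544 with an estimated correlation); scl-9, scl-15 and scl-25 are among the 54 genes near 0 in wild type. Called genes were spread over the chromosomes, with 41.4% of tested genes called on chromosome IV (adjusted p = 0.00569 by Fisher's exact test), 47.1% on V (adjusted p = 0.00731), 41.8% on X (adjusted p = 0.0263) and 2 of 17 on the mitochondrial genome (adjusted p = 0.0146). Only 2 chromosomes passed without mutant 2 or without wild type 5.

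Among 100 of the 126 splits of the libraries into 5 and 5, the real split alone (1 split) gave as many genes that rose (3069) or fell (3303). The same held for genes that rose (272) or fell (435) at least 2-fold. The highest count of any other split was 2 in each case, so a chance division of these libraries is excluded for these counts. A chance difference between cultures is not excluded, since libraries of a group may share a culture. The class scan gave 23 classes, and 2 splits, the real one included, gave as many (highest other 24). That share is under 0.05, but 1 other split gave more classes than the real one. The splits therefore do not firmly exclude chance for the class scan. For the list counts chance is not excluded: 96 splits gave at least 3 lists higher (highest other 15) and 6 gave at least 13 lists lower (highest other 15).

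Males or male tissue in the mutant cultures are a candidate explanation for the 54 genes near 0 in wild type. The 11 male-restricted markers had a median log2 fold change of 0.22 (SE 0.311, and 0.82 as a log2 ratio of group means), 10 lay above 0 and 4 had no overlap between groups. All 3 that could be tested rose (cwp-1, cwp-2 and try-5, the last at 6.88 ± 1.26 FPKM against 4.59 ± 0.730). Of these, cwp-1 and cwp-2 reached the filter only through the mutant libraries, so the filter itself favoured a rise for them. Linkage to the edited gene is argued against, since 9.26% of the set lay on chromosome I. Sperm genes leave the male explanation open: 11 spermatogenesis genes had a median change of 0.085 (SE 0.0645) and major sperm proteins one of -0.31 (SE 0.0899), but wild type libraries hold 28.2 FPKM of the latter on average, which could hide a small share of males. An effect of the genotype on these genes was not tested apart from this. The male markers share no single ratio of mutant 5 to mutant 1 (plg-1 0.365, asic-2 1.13, cwp-4 1.33, try-5 and lov-1 1.47, pkd-2 1.95, trf-1 2.35, cwp-1 3.11, cwp-2 3.13, cwp-5 4.75). Of these, all but try-5, cwp-1 and cwp-2 averaged below 1 FPKM in the mutant, so their ratios are imprecise and decide little. scl-25, at 0.994, lies apart from the other 53 genes of the set. The SEs of the medians above take genes as independent and can be too small. Major sperm proteins had an estimated correlation of 0.816.

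The lower level of cytosolic ribosomal protein genes may come from a loss of short, abundant transcripts. Their median (-0.20) lay at percentile 74.9 of 10000 lists of other genes matched on exon length and level, which had a median of -0.23. They therefore fell no further than most of these lists. The match was incomplete, with a median exon length of 532 bases against 617 in the matched pool. The median log2 level was 11.02 against 10.55. The 236 distinct genes of the pool had a median change of -0.16, so the ribosomal genes fell further than the pool as a whole. The sign of the ribosomal median also turned with quantile normalisation (median 0.029). Across genes, the change went only weakly with exon length (rho 0.106). The matching cannot tell a loss of transcripts from a change shared by abundant genes. An effect of the genotype on ribosomal genes stays open and untested.

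A lower share of germline tissue alone is argued against as the source of the lower germline, oocyte and eggshell markers. It would raise the markers of all other tissues alike, but these moved apart: the 36 muscle and intestine markers had a median change of -0.42 (SE 0.0708), while neuron markers, at 0.13 (SE 0.0687), and neuropeptide genes, at 0.15 (SE 0.0762), went the way it needs. These SEs take genes as independent and can be too small, as the estimated correlation was 0.614 among muscle and 0.0126 among intestine genes. In the gene tests, which use the spread between libraries, 12 of 19 muscle genes fell and 0 rose. Of 17 intestine genes, 8 fell and 1 rose. A lower germline share together with changes in those tissues, and an effect of the genotype on germline genes, stay open and untested.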
